A study of Mus musculus with 15 samples.

How the data were processed

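The series holds single-cell RNA sequencing of mouse embryonic tissue. Per the labels, placental cells were sorted and run on the 10x Genomics droplet platform at embryonic days 10, 11 and 12, with 1 sample each. Hoxa13-lineage GFP cells of the placenta are listed as 4 samples at day 11, 2 at day 12 and 1 at day 13.5. A further 5 samples at day 11 (hemogenic and non-hemogenic endothelium of placenta and AGM, and yolk sac endothelium, with 1 sample each) were not analysed here.

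The droplet matrix holds raw UMI counts per gene and cell as deposited by the authors, checked as whole numbers whose sums per cell equal the total the deposited annotation gives. The same deposited annotation gives a class per cell (EC, HSC, TC, Stromal, Pre or none) and the percent of mitochondrial UMIs. EC was read as endothelial cells, and the other names were kept as they stand. The Hoxa13 GFP table holds raw counts per gene and cell as deposited by the authors. Whether reads or molecules were counted in it is not given in the sources used here. Per the submitters' processing notes, Cell Ranger, HISAT2, HTSeq and the mm10 genome were used. Their versions and roles, and the filters on cells, are not given in the sources used here.

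Cell names in the droplet matrix end in 1, 2 or 3, called sets 1, 2 and 3 here. No label ties a set to a day, so no comparison between days was made. Cell names in the GFP table carry 7 suffixes (CD31, CD31N, CD31P, CD45P, FITC, HE and HSC) that no label ties to a sample. Since unmapped sets are not replicates, the tests that the design named before the data were examined (edgeR quasi-likelihood, gene set tests and permutation tests) were not run. No p-value and no count of genes past a threshold is given. The comparisons between days in placenta and GFP cells, and a comparison of annotated hemogenic endothelium, which the annotation does not name, were left out. Among the GFP suffixes, 0 held 5 cells of both macrophage-like and endothelial-like cells, so these were not compared by suffix either.

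Levels are CPM, the counts of a gene scaled to the UMIs of the summed cells as edgeR does. For each set and class, UMIs were summed over cells and scaled with TMM factors from edgeR 4.0.16 in R 4.3.3 after its default expression filter. The sets were then given equal weight. Intervals of 95% are exact Poisson limits for a sum in 1 set, Fay-Feuer limits for a level over sets, and exact Clopper-Pearson limits for shares. They cover counting error only, not variation between animals. A ratio against 0 UMIs is given as a lower limit from these intervals. Levels of a class or cluster outside the 2 comparisons, such as those of TC-labelled cells, were not TMM-scaled. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 did the rest.

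For the call of Cd44, each EC-labelled cell was thinned to 9145 UMIs, the 25th percentile. The 682 shallower cells were left out and 2044 were kept. A cell with at least 1 Cd44 UMI after thinning was called Cd44-positive, and full counts were summed. Background was read from TC-labelled cells thinned in the same way.

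Cells of each label were clustered with 1500 variable genes, 20 principal components, 15 neighbours and Leiden resolution 1, with resolution 2 as an alternative. Markers were counted per cluster when above 20 CPM and more than 1 log2 unit above the other cells of the label, with an offset of 20 CPM. A cluster took the name of a cell type with at least 4 such markers and 1.5 times those of the next type, unless its 10 top genes pointed elsewhere. For the GFP table, cells with 1000 genes or more were clustered with 15 principal components and 10 neighbours. The naming rule, the GFP clustering settings (chosen among several tried), the limits for arterial clusters (6 arterial markers) and clusters with markers of another type (4), and the choice of list medians as lead values were set after the data were seen. No doublet caller was run. A cap at 2 times the median UMIs and the removal of clusters with markers of another type stood in for it.

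The 22 gene lists hold 218 symbols, of which 1 was missing from the droplet matrix and 6 from the GFP table. A list's median log2 ratio was taken over members with 100 UMIs or more, given a 95% range from 500 Poisson redraws, and placed among 10000 random lists matched on mean expression. A member counts as higher when it is higher in every set, which coin flips would give in 12.5% of genes for 3 sets and 25% for 2. The share among all genes is not given here, so counts of members describe the lists only. Named genes are, per list, up to 2 members with intervals that do not overlap and the largest ratio, then the 5 genes of highest and lowest ratio with 200 UMIs or more, leaving out hemoglobin, mitochondrial, ribosomal and unnamed (Gm) genes, plus a fixed list of 14 genes. Members named beyond that rule were chosen after their values were seen. Macrophage and endothelial lists named the clusters, so their levels describe the classes and are not results.

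The ratios were tested on simulated counts with 200 changed genes, drawn as Poisson counts and scaled by plain totals. The simulation therefore checks the ratio and interval code only, not TMM scaling, spread between cells or doublets. In the Cd44 comparison, over 10159 genes, simulated log2 ratios of 1, 2, -1 and -2 came back as 0.98, 1.99, -1.003 and -1.93. Intervals were apart for 98% and 100% of the higher genes but 82% and 90% of the lower ones, and 0.462% of 9959 unchanged genes had intervals apart. In the macrophage comparison, over 9162 genes, they came back as 1.02, 2.02, -1.04 and -2.02, apart for 100% and 100% of higher and 78% and 98% of lower genes, with 0.558% of 8962 unchanged genes apart.

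Alternatives were RLE factors, plain totals, no expression filter, sums over sets, each set left out, the UMI cap, cells without blood transcripts, the Cd44 call on unthinned counts, thinned counts summed, cells with 6 or more eGFP UMIs, and other cluster settings. Gene positions come from the GENCODE annotation of GRCm38 (mm10), matched by the Ensembl identifiers in the matrix.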

Results

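The droplet data held 17386 placental cells and 28694 genes in 3 barcode sets. Set 1 had 3091 cells and 59430556 UMIs, set 2 had 8307 cells and 190750859 UMIs, and set 3 had 5988 cells and 130158070 UMIs. The median depth was 15496, 21292 and 20086.5 UMIs per cell. The authors named 16205 of these cells (93.2%). The Hoxa13 GFP data held 19166 genes in 672 cells, with 96 cells for each of 7 suffixes and totals from 695658 to 5357277 counts per suffix. There are no replicates tied to a group in either table, so every difference below is a description of these cells, and each interval covers counting error alone.

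The first question was which cell classes make up the placenta samples. Endothelial cells (EC) made up 56.4% of set 1 (95% interval 54.6 to 58.1) but 7.98% of set 2 (7.41 to 8.58) and 5.34% of set 3 (4.79 to 5.94). HSC-labelled cells made up 8.19% (7.24 to 9.21), 72.0% (71.0 to 72.9) and 35.0% (33.8 to 36.2) of sets 1, 2 and 3. TC-labelled cells made up 23.6% (22.1 to 25.1), 17.4% (16.6 to 18.3) and 44.9% (43.7 to 46.2). Stromal cells were at most 2.15% and Pre cells at most 0.885% of a set. The day of each set is not given in the sources used here, and sorting came before loading, so these are shares of the loaded cells.

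**Figure D1:**
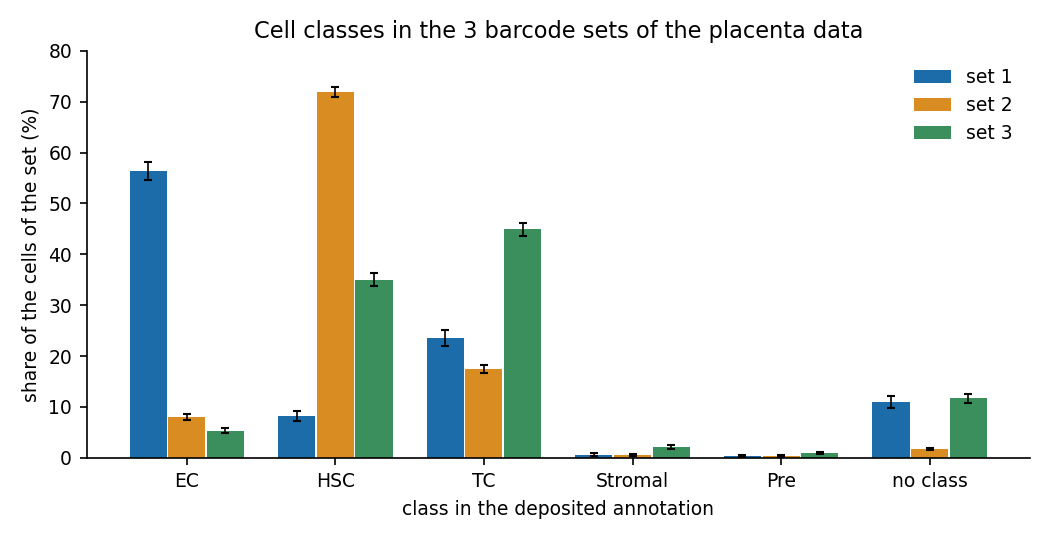
Share of cells of each deposited class (percent of the set's cells) in the 3 barcode sets; bars are shares and whiskers exact 95% binomial intervals. EC-labelled cells lead set 1 with 56.4%, HSC-labelled cells set 2 with 72.0%, and TC-labelled cells set 3 with 44.9%.

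The HSC label covered several cell types. Endothelial-like clusters of 253 and 50 cells, the smaller with 9 arterial markers raised, and a trophoblast-like cluster of 116 cells lay under it beside the blood lineages. The cluster of 253 cells also had 6 MHC class II and 3 macrophage markers raised, with Cd74 and H2-Aa among its top genes. It may be mixed, which was not tested. Megakaryocyte-like clusters, marked by Pf4, Ppbp and Gp9 of the platelet lineage, held 54.5% of HSC-labelled cells in set 1 (48.2 to 60.8), against 4.38% in set 2 (3.88 to 4.93) and 4.58% in set 3 (3.73 to 5.56). A granulocyte-like cluster with Elane, Mpo and Prtn3, which encode neutrophil granule proteins, held 715 cells, 712 of them in set 2. At resolution 2 that name went to 312 cells, and a cluster of 349 cells with Prtn3 and Mpo took no name. Another unnamed cluster of 415 cells with Mpo and Perp among its top genes had 414 cells in set 3. Over all HSC-labelled cells, Mpo stood at 338 CPM in set 2 and 293 CPM in set 3. It had a UMI in 82.6% and 69.1% of these cells. Clusters were drawn over the sets without correction and often split by set, so granulocyte-like cells are not shown to be absent from set 3. Macrophage-like cells with C1qa, C1qb, Apoe and Aif1 numbered 0 of 253 in set 1, which allows a share of up to 1.45%, 158 of 5978 in set 2 (2.64%, 2.25 to 3.08) and 87 of 2096 in set 3 (4.15%, 3.34 to 5.09). A cluster of 394 cells led by Irf8, a regulator of monocyte development, took no name. At resolution 2 the macrophage-like clusters grew to 500 cells and included the 245.

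Hoxa13, a homeobox gene at chromosome 6, 52257694 to 52260880 (mm10, minus strand), was highest in EC-labelled cells among the 3 large classes. It stood at 10.5 CPM (9.32 to 11.9), 14.4 CPM (12.0 to 17.0) and 11.1 CPM (7.95 to 15.03) in the EC-labelled cells of sets 1, 2 and 3. It was at most 0.555 CPM in HSC-labelled and 0.422 CPM in TC-labelled cells. In Stromal cells it was lower than in EC-labelled cells in sets 2 and 3, with intervals apart. Set 2 had 0 UMIs in 46 cells (up to 6.66 CPM) and set 3 had 2 UMIs in 129 cells (1.16 CPM, 0.141 to 4.19). Set 1 leaves it open, with 2 UMIs in 17 Stromal cells (7.72 CPM, 0.935 to 27.9). Runx1 (chromosome 16, 92601466 to 92826149), the transcription factor of blood cell emergence, had a UMI in 1.84%, 4.83% and 4.06% of EC-labelled cells at medians of 12987, 11701 and 9316 UMIs. TC-labelled cells, at 27213, 26797 and 24198 UMIs, had it in 1.24%, 10.9% and 6.21%, and these shares are not comparable at such different depths. By level, Runx1 stood in EC-labelled against TC-labelled cells at 1.28 CPM (0.884 to 1.80) against 0.563 CPM (0.291 to 0.983) in set 1, 4.27 CPM (3.04 to 5.84) against 5.26 CPM (4.60 to 5.98) in set 2 and 4.32 CPM (2.47 to 7.02) against 3.20 CPM (2.80 to 3.65) in set 3, with overlapping intervals in each set. In HSC-labelled cells it was found in 71.1%, 78.2% and 74.0%.

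The series names placental hemogenic endothelium as a population of its own, so endothelial cells with and without Cd44 transcripts were compared. Cd44 (chromosome 2, 102811141 to 102901665), which encodes a hyaluronan receptor, was detected after thinning in 11.5% of endothelial cells in set 1 (156 of 1360, 9.82 to 13.3), 32.2% in set 2 (165 of 513, 28.1 to 36.4) and 27.5% in set 3 (47 of 171, 20.9 to 34.8). Thinned TC-labelled cells had it in 0.433%, 3.92% and 1.97%. Before thinning these cells were deeper, with medians of 27213, 26797 and 24198 UMIs against 12987, 11701 and 9316 in EC-labelled cells. Free RNA may be a smaller part of their UMIs, so this background may be too low for endothelial cells. Cd44-positive endothelial cells had an arterial profile: the 12 measured members of the arterial list were each higher than in Cd44-negative cells in each of the 3 sets. Their median log2 ratio was 1.11 (1.01 to 1.23), above all of the 10000 matched random lists.

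Gja5, an arterial gap junction gene (chromosome 3, 96904693 to 97077416), stood at 355 CPM (340 to 372) in Cd44-positive and 91.8 CPM (86.7 to 97.2) in Cd44-negative cells. Cxcr4, the receptor of the chemokine Cxcl12, stood at 10.3 CPM (7.75 to 13.7) against 2.34 CPM (1.57 to 3.53). The Notch ligand gene Dll4 was at 98.1 against 44.0 CPM, and Hey1, a Notch target, at 156 against 54.0 CPM. Venous genes were lower or mixed, with a list median of -0.35 (-0.54 to -0.19) and 3 of 6 members lower in each set. Nr2f2, the venous identity factor, was at 10.9 CPM (7.60 to 15.3) against 19.5 CPM (16.9 to 22.5), and the apelin receptor gene Aplnr at 150.4 CPM (138 to 164) against 253 CPM (244 to 262).

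**Figure D2:**
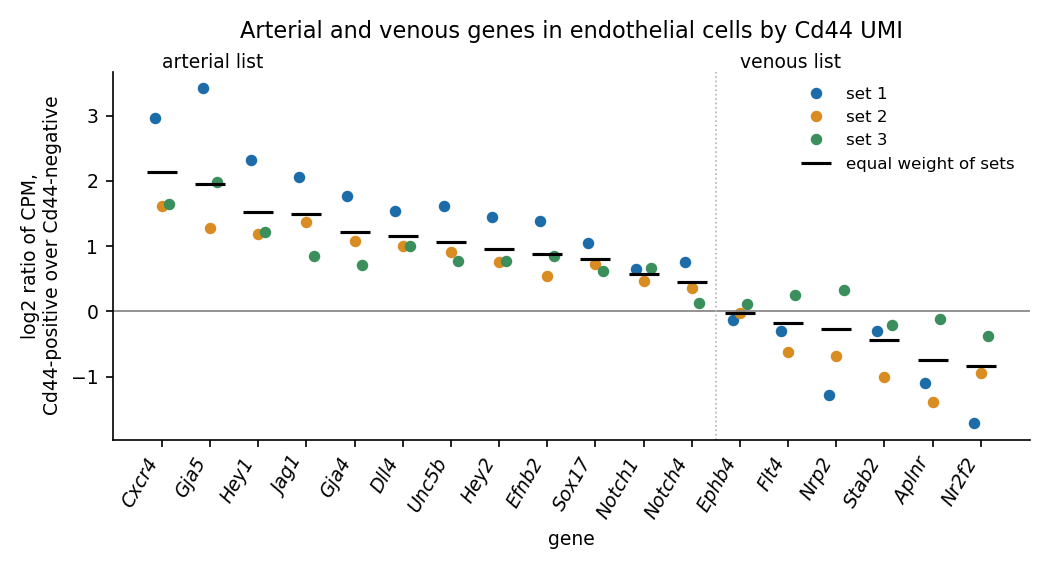
Log2 ratio of CPM in Cd44-positive over Cd44-negative endothelial cells for the genes of the arterial and venous lists; points are the 3 barcode sets and black lines the ratio at equal weight of the sets. The 12 arterial genes lie above 0 in each set, with Cxcr4 at 2.13 and Gja5 at 1.95, and the venous Nr2f2 lies at -0.84.

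Among blood regulators, 4 of the 9 members with enough UMIs were higher in each set (Spi1, Tal1, Gata2 and Mecom) and 1, Cd34, was lower, with a list median of 0.29 (0.03 to 0.39). Mecom (chromosome 3, 29951296 to 30548008), a transcription factor gene active in blood stem cells and in arterial endothelium, had the largest ratio, at 92.0 CPM (83.9 to 101) against 31.8 CPM (28.6 to 35.4). Gata2 was at 71.6 CPM (63.8 to 80.3) against 53.9 CPM (49.7 to 58.4). Runx1 was at 4.34 CPM (2.53 to 7.26) against 3.14 CPM (2.05 to 4.70), a difference not detectable at this depth. This holds for EC-labelled cells only. The endothelial-like clusters of 253 and 50 cells under the HSC label had Runx1 at 51.5 and 49.5 CPM without TMM scaling. Their Cd44 stood at 75.1 and 90.1 CPM. Whether these clusters hold doublets was not tested. Kit, a growth factor receptor gene, was at 26.0 CPM (20.9 to 32.1) against 28.6 CPM (25.7 to 31.9). Gfi1, a target of Runx1, had 0 UMIs in Cd44-positive cells, which allows up to 1.62 CPM. Ptprc, Csf1r, Cx3cr1, Adgre1 and Mrc1 were each under 4 CPM on either side, and Lyve1 was at 161 against 152 CPM.

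Angiogenic factors went both ways, with a list median of 0.24 (0.04 to 0.41). The chemokine gene Cxcl12 was at 133 CPM (124 to 144) in Cd44-positive cells against 38.5 CPM (35.3 to 42.1), and the growth factor gene Igf1 at 19.4 CPM (15.5 to 24.2) against 49.9 CPM (45.9 to 54.3). In the stromal and allantoic list, 4 of 5 members were higher in each set, among them Hoxa13 at 17.0 CPM (13.2 to 21.9) against 10.7 CPM (8.94 to 12.8), and the list median was 0.64 (0.31 to 0.79). The Notch targets Nrarp (170.02 against 121 CPM) and Hes1 (181 against 149 CPM) were higher in each set, but without cells over 2 times the median UMIs the log2 ratio of Hes1 was -0.021. Dissociation stress genes were higher in 6 of 9 members, with a median of 0.29 (0.24 to 0.38); Fos stood at 272 against 190 CPM and Egr1 at 73.2 against 39.7 CPM. Cell cycle genes had a median of -0.21 (-0.28 to -0.13) with 4 of 12 members lower in each set, Mcm5 among them at 71.7 against 91.7 CPM. The glycolysis median was 0.02 (-0.09 to 0.07), with Slc2a1 at 87.5 against 60.5 CPM and Pkm at 418 against 480.4 CPM. The pan-endothelial list had a median of 0.09 (0.05 to 0.14); Cdh5 was at 645 against 535 CPM, Pecam1 at 658 against 615 CPM, Flt1 at 316 against 231 CPM and Emcn at 394 against 607 CPM.

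Among all genes with 200 UMIs or more, the highest ratios were those of Sox6 (23.4 against 4.54 CPM), Bmx (27.0 against 5.52 CPM), Vldlr (25.7 against 6.42 CPM) and the trophoblast genes Tpbpb (90.8 against 19.2 CPM) and Ceacam11 (32.1 against 7.99 CPM). The last 2 were higher in 2 of the 3 sets. Ceacam11 fell to a log2 ratio of -0.18 with a set left out, and Tpbpb reversed without clusters with markers of another cell type. The lowest were Ctsr (1.85 against 34.7 CPM), Prl4a1 (1.08 against 8.62 CPM), Ctsj (9.43 against 40.3 CPM), Chchd10 (3.82 against 19.9 CPM) and Cd74 of the MHC class II list (5.03 against 42.7 CPM). Prl4a1 was lower in set 1 alone, with a log2 ratio of 0.026 without it, and Ctsr and Chchd10 owed most of their ratios to set 3 (3.95 against 101 CPM and 3.95 against 50.3 CPM). Ctsj was at 9.41 against 29.9 CPM in set 1, 3.09 against 4.36 CPM in set 2 and 15.8 against 86.7 CPM in set 3. The low ratios of Ctsr, Ctsj and Prl4a1 are not read as endothelial differences. Other list members named were Bmp2 of the decidual list (36.8 against 77.4 CPM), S100a4 (19.6 against 7.94 CPM) and Ebf1 (85.7 against 58.2 CPM). Krt8 (32.6 against 81.9 CPM) turned to the other direction without cells over 2 times the median UMIs (0.74), without blood transcripts (0.56) and with thinned counts (0.23). Markers of other cell types differed between the arms in some sets only, as Tpbpa (718 against 328 CPM), Prtn3 (20.5 against 6.17 CPM), Mpo (12.2 against 4.33 CPM), Ppbp (59.5 against 23.1 CPM), Plac8 (117 against 202 CPM) and Hba-a1 (14.3 against 119 CPM) did. In set 3, 29.8% of Cd44-positive and 24.2% of Cd44-negative cells lay in clusters with markers of another cell type, and the MHC class II median of -3.09 was 0.14 without these clusters, an alternative chosen after the data were seen.

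The arterial difference followed clusters of endothelial cells. A pair of clusters with Gja5, Serpinf1, Fbln2, Vwf and Cxcl12 among their top genes held 448 of the 2726 EC-labelled cells. Both had 9 arterial markers raised, and cluster 5 (232 cells) also had 7 dissociation stress markers raised, against 0 in cluster 6 (216 cells). Of their thinned cells, 55.2% were Cd44-positive (187 of 339, 49.7 to 60.5), against 10.6% of the others (181 of 1705, 9.19 to 12.2). Within set 1 the shares were 54.8% and 7.12%, within set 2 55.0% and 17.4%, and within set 3 61.5% and 24.7%. Outside these clusters the arterial list kept a median of 0.69 (0.53 to 0.83), with 11 of 12 members higher in each set. Inside them, in sets 1 and 2, the median was 0.06 (0.01 to 0.15), and Gja5 was at 829 CPM (793 to 865) in Cd44-positive and 808 CPM (769 to 849) in Cd44-negative cells. This split was chosen after the data were seen. Without set 1 the median over all endothelial cells was 0.93.

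**Figure D3:**
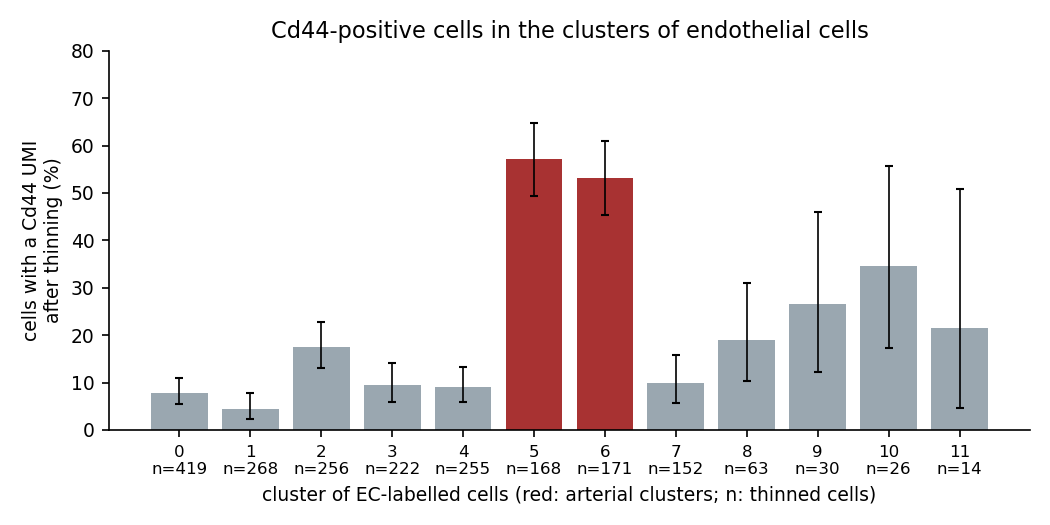
Share of thinned EC-labelled cells with a Cd44 UMI (percent) in each cluster of endothelial cells; whiskers are exact 95% binomial intervals and n is the number of thinned cells. The arterial clusters 5 and 6, in red, stand at 57.1% and 53.2%.

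The study's title asks about macrophages, so the 245 macrophage-like cells were compared with EC-labelled cells in sets 2 and 3, which hold them. Blood regulators split. Of 13 members, 6 were higher in both sets (Runx1, Spi1, Lmo2, Cd44, Ptprc and Ikzf1) and 6 lower (Tal1, Gata2, Kit, Itga2b, Mecom and Cd34), with a list median of 0.54 (0.35 to 0.74). The sign of that median rests on set 3, without which it was -0.017. Spi1, the master regulator of myeloid cells, stood at 575 CPM (549 to 602) against 7.51 CPM (6.07 to 9.24). Runx1 stood at 91.2 CPM (80.4 to 103) against 3.72 CPM (2.72 to 5.01), and Ptprc, which encodes CD45, at 81.0 CPM (71.4 to 91.6) against 2.34 CPM (1.51 to 3.49). Cd44 was at 132 CPM (120.3 to 145) against 43.3 CPM (39.7 to 47.1). Mecom was at 3.02 against 49.2 CPM, Gata2 at 8.42 against 52.1 CPM and Kit at 11.7 CPM (7.96 to 16.6) against 21.1 CPM (18.6 to 24.0), while Gfi1 was at 1.08 CPM (0.350 to 3.02) against 0.259 CPM (0.0595 to 0.810), not separable at this depth. Runx1 is not particular to macrophage-like cells. Without TMM scaling it was at 72.4 CPM in them, and at 90.5, 118 and 71.1 CPM in HSC-labelled clusters of 992, 920 and 828 cells. Spi1 was at 513 and 481 CPM in macrophage-like cells of sets 2 and 3, against 254 and 226 CPM in all HSC-labelled cells. Ptprc was at 77.0 and 62.7 CPM, against 36.7 and 43.3 CPM.

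Macrophage-like cells carried little or no transcript of Hoxa10, Hoxa11 and Hoxa13. Hoxa13 had 0 UMIs, which allows up to 1.59 CPM, against 11.0 CPM (9.29 to 13.02) in endothelial cells, at least 5.82-fold lower. Hoxa11 also had 0 UMIs, at least 5.91-fold lower, and Hoxa10 stood at 0.864 CPM against 30.7 CPM. Of the monocyte list, 4 of 6 members were higher in both sets, with a median of 3.20 (2.97 to 3.44); Itgam was at 45.8 against 0.981 CPM and the chemokine receptor gene Ccr2 at 94.3 against 2.85 CPM. Glycolysis genes were higher in 7 of 9 members, with a median of 1.20 (0.91 to 1.31), Hk2 at 62.4 against 3.75 CPM and Eno1 at 372 against 125 CPM. Dissociation stress genes were higher in 9 of 9, with a median of 1.48 (1.25 to 1.58), Fos at 747 against 214 CPM and Hspa1a at 362 against 88.3 CPM. Cell cycle genes had a median of 0.33 (0.20 to 0.41) with 8 of 12 higher, such as Aurkb (85.5 against 49.2 CPM) and Mcm5 (117 against 71.6 CPM), but plain totals turned this median to -0.087, so its direction rests on the scaling.

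Angiogenic factors divided between the classes, with a median of -2.48 (-2.64 to -2.28). Vegfb (22.0 against 10.8 CPM), Igf1 (64.4 against 29.7 CPM), Tgfb1 (293 against 133 CPM) and Thbs1 (27.6 against 8.78 CPM) were higher in macrophage-like cells in both sets. Cxcl12 (0.648 against 68.8 CPM), Pdgfb (3.46 against 56.2 CPM), Nrp1 (110 against 611 CPM), Hbegf and Angpt2 were lower. The Notch targets Hes1 (17.1 against 148 CPM) and Nrarp (2.81 against 103 CPM) were lower. MHC class II genes had a median of 2.87 (2.71 to 3.18); Cd74, the invariant chain gene on chromosome 18, was at 268 CPM (248 to 290) against 30.4 CPM (27.0 to 34.2), and H2-Eb1 at 93.4 against 9.52 CPM, higher in 1 of the 2 sets. The summed class II level of macrophage-like cells was 98.1 CPM in set 2 (86.8 to 111) and 1052 CPM in set 3 (997 to 1109), while the medians per cell were 0.593 and 0.621 UMIs per 10000 UMIs, so few cells carried the difference.

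As identity of the classes, C1qa (750 against 0.144 CPM), Csf1r (325 against 1.76 CPM), Cx3cr1 (355 against 0.835 CPM), Adgre1 (94.8 against 0.375 CPM) and Mrc1 (211 against 2.07 CPM) were high in macrophage-like cells, as were Fcrls (at least 425 times the endothelial level), Mcemp1 (at least 168 times), Ccl12 (at least 411 times) and Trem2 (at least 359 times), each with no more than 3 UMIs in endothelial cells. Lyve1 was at 76.1 CPM (65.3 to 88.2) against 146 CPM (139 to 154), with 2.59 against 81.2 CPM in set 2 and 149.6 against 211 CPM in set 3. Cdh5 (8.86 against 493 CPM), Pecam1 (9.72 against 582 CPM), Gja5 (0.216 against 159 CPM), Hey1 (0.216 against 80.9 CPM), Ephb4 (0.648 against 51.9 CPM), Flt4 (0.647 against 45.3 CPM), Fhl1 (0.431 against 296 CPM), Tmem100 (0.864 against 496 CPM), Stmn2 (1.08 against 580.2 CPM) and Vwf (0.216 against 102 CPM) were low. Some members of the granulocyte, megakaryocyte, B cell and erythroid lists stood higher in macrophage-like cells: S100a8 (589 against 3.61 CPM), S100a9 (396 against 3.56 CPM), Pf4 (1239 against 156 CPM), Ighm (243 against 2.05 CPM), Cd79b (75.8 against 10.1 CPM), Hbb-bs (1844 against 2.30 CPM) and Hba-a2 (923 against 5.10 CPM). Set 3 carried the globins and Pf4: in set 2 Pf4 was at 195 against 128 CPM, Hbb-bs at 5.18 against 1.82 CPM and Hba-a2 at 11.6 against 0.959 CPM. Trf of the endoderm list was higher (124 against 34.0 CPM). Itgb3 of the megakaryocyte list (1.51 against 12.998 CPM), Gata3 (1.95 against 9.81 CPM), Hand1 (3.02 against 14.97 CPM) and Bmp2 (3.89 against 41.7 CPM) were lower. Plain totals in place of TMM moved the median of all genes from -0.08 to -0.50, so ratios are relative to TMM, and the blood regulator median was -0.02 without set 3 and 1.002 without set 2.

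The TC-labelled cells, used above as background, carried Cdh5, the gene of VE-cadherin, at 224 CPM (217 to 230.09), 186 CPM (182 to 190.08) and 142 CPM (139 to 145) in sets 1, 2 and 3. That is 41.6%, 29.8% and 25.9% of its level in EC-labelled cells outside clusters with markers of another type. Flt1, which encodes a VEGF receptor, stood at 42.3%, 137% and 122% of the endothelial level and Esam at 20.3%, 14.4% and 12.6%. Pecam1 stood at 5.80%, 1.99% and 1.48%, and Cldn5 at no more than 1.96%. The comparison was chosen after the data were seen.

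**Figure D4:**
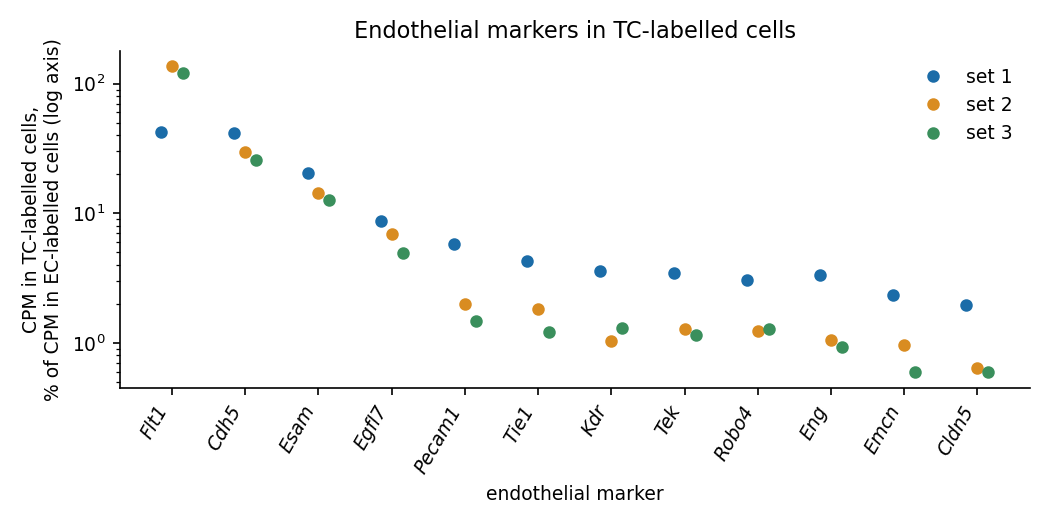
Level of each of the 12 endothelial markers in TC-labelled cells as percent of its level in EC-labelled cells (log scale), for the 3 barcode sets. Cdh5 stands at 41.6%, 29.8% and 25.9%, and the median of the other 11 markers at 3.61%, 1.28% and 1.28%.

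The Hoxa13 GFP cells were asked for the classes that carry the lineage label. Of 490 cells with 1000 genes or more, 84 were endothelial-like (17.1%, 13.9 to 20.8), 66 stromal-like with Col1a1 and Col3a1 (13.5%, 10.6 to 16.8), 55 mast or basophil-like with Cpa3 and Mcpt8 (11.2%, 8.57 to 14.4), 25 trophoblast-like (5.10%, 3.33 to 7.44), 19 macrophage-like (3.88%, 2.35 to 5.99) and 5 megakaryocyte-like. The other 236 took no name. Their 4 clusters, of 88, 61, 54 and 33 cells, had a Cdh5 count in 81.8%, 90.2%, 79.6% and 90.9% of cells. Those of 61 and 54 cells also had a Ptprc count in 78.7% and 74.1%, so a Cdh5 count alone does not mark endothelium in this table. Those of 88 and 33 cells had a Ptprc count in 4.55% and 0%. They had a Pecam1 count in 95.5% and 97.0% of cells, at means of 932 and 1591 CPM against 1348 CPM in endothelial-like cells. Their Plvap means were 934 and 3853 CPM against 2074 CPM. Both clusters thus look endothelial, though the naming rule, which compares each cluster with all other cells, gave them no name. The 17.1% counts the named clusters only and is likely too low for endothelial cells. The endothelial-like share was 5.18% with 2000 genes or more per cell and 32.4% by marker score. Of the macrophage-like cells 14 bore the suffix HSC (15.4% of its cells, 8.67 to 24.5), 4 the suffix CD45P and 1 the suffix CD31. Stromal-like cells made up 60.9% of the suffix CD31N and 43.0% of FITC, and mast or basophil-like cells 60.0% of CD45P.

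An arterial cluster also stood out in the GFP data. It held 31 cells, 23 of them with the suffix HE (31.9% of its cells, 21.4 to 44.0). Its top genes included Mecom (mean 1228 CPM), Gja5 (mean 1117 CPM), Vwf, Serpinf1 and Cxcl12. Cd44 had a count in 64.5% of its cells (45.4 to 80.8), against 13.2% (5.48 to 25.3) in the other endothelial-like cluster, at median depths of 13800 and 6508 counts. Runx1 had a count in 12.9% (3.63 to 29.8) of arterial-cluster cells and 68.4% (43.4 to 87.4) of macrophage-like cells. The eGFP transcript had a mean of 1072 CPM in endothelial-like and 154 CPM in macrophage-like cells, where 52.6% of cells (28.9 to 75.6) had a count. Cdh5 had a count in 73.7% of macrophage-like cells and Col1a1 in 78.9%, so markers of other types were found in most of these cells and a count of eGFP in a cell does not by itself place it in the lineage. The macrophage-like share was 0% with 2000 genes or more per cell and 10.2% at 2 times the resolution, so its size changed with the gene filter and with the resolution.

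**Figure D5:**
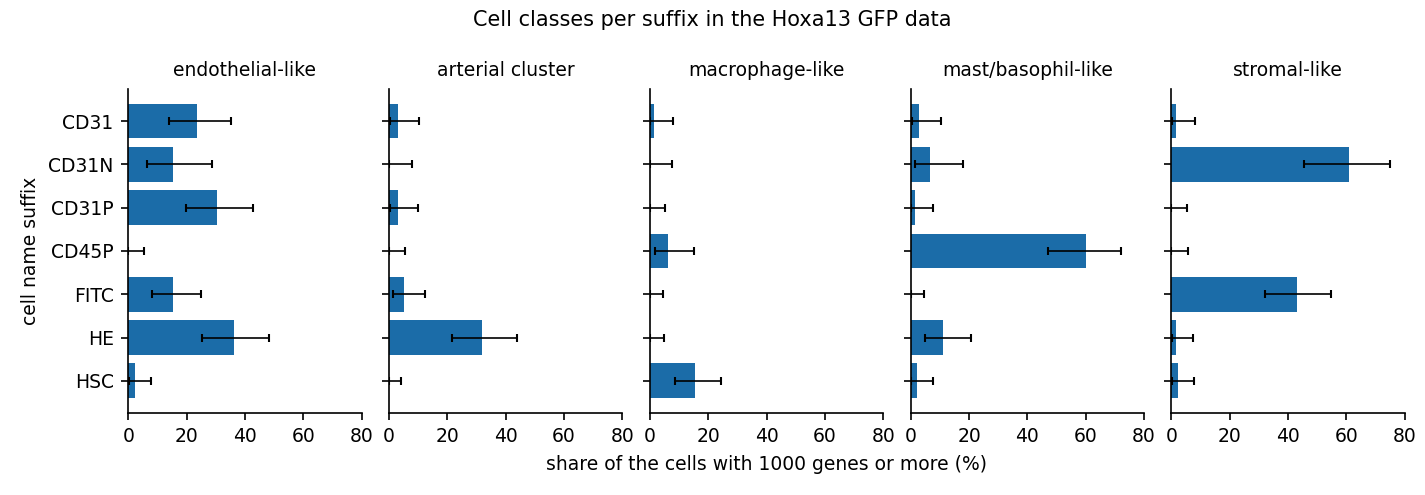
Share of cells in 5 classes (percent of cells with 1000 genes or more) for each of the 7 suffixes of the Hoxa13 GFP cells; the arterial cluster is part of the endothelial-like class, and whiskers are exact 95% binomial intervals. The suffix HE holds 31.9% arterial-cluster cells and the suffix HSC 15.4% macrophage-like cells. The endothelial-like class counts named clusters only, and unnamed clusters with endothelial markers are outside it.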

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

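The looks at cells without a class were chosen after the results were seen. A class was missing for 1181 droplet cells, of which 675 had 0 eGFP UMIs and 512 had a mitochondrial share of 9% or more, while 0 of the 16205 cells with a class had either. These cells are outside the comparisons of the report, and 810 of the 1181 (68.6%, 65.9 to 71.2) took no name. Macrophage-like cells numbered 44 of the 1181 (3.73%, 2.72 to 4.97), 42 in set 3. Their MHC class II level was 5889 CPM (5683 to 6101), and 40 of the 44 had 0 eGFP UMIs. Within set 3 it was 6109 CPM (5894 to 6328), against 1052 CPM (997 to 1109) in the macrophage-like cells with a class. At resolution 2 the unclassed cells gave a macrophage-like cluster of 35 cells with C1qa at 0 and Cd74 at 8525 CPM, another of 20 cells with C1qa at 2082 and Cd74 at 955 CPM, and an unnamed cluster of 24 cells with 11 macrophage and 10 endothelial markers, C1qa at 68.3 and Cd74 at 3690 CPM, so the name and the 44 cells may not stand for 1 cell type, which was not tested. Endothelial-like cells numbered 222 (18.8%, 16.6 to 21.1), of which 36.9% (30.6 to 43.7) had an eGFP UMI. Since a missing eGFP UMI sets the unclassed cells apart by itself, the eGFP shares of the classes say nothing about lineage.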

How the results depend on the processing

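Of the values that lead each comparison, 36 stayed within the limits set for a move, 11 moved and 1 reversed, and of the other values 1307 stayed, 278 moved and 26 reversed. The arterial list kept 12 of 12 members higher in each set of Cd44-positive cells under each of the alternatives for all endothelial cells but thinned counts, where 11 were higher. In the split by arterial clusters, 11 of 12 were higher outside them and 5 of 12 inside.

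Without cells over 2 times the median UMIs, HSC-labelled cells were 73.5% of set 2 and 36.3% of set 3, and TC-labelled cells 16.5% of set 2. A filter at 2000 UMIs removed no cell, so the EC, HSC and TC shares under it could not move, though they count above among the values that stayed. In the GFP cells, the endothelial-like share was 5.18% with 2000 genes or more per cell and 32.4% when each cell took its highest marker score. The macrophage-like share was 0% with 2000 genes or more and 10.2% at 2 times the resolution. The cause was not tested.

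For Cd44-positive against Cd44-negative endothelial cells, counts summed over sets with no replicate block gave an arterial median of 1.42, with the erythroid median at 0.084 and Plac8 at 0.57, both reversed. Set 1 holds most of the Cd44-negative cells, so a sum mixes sets with cell state. With each set left out in turn, the arterial median ran from 0.93 to 1.22, Plac8 from -1.17 to 0.82, Hba-a1 from -3.35 to 0.061, Tpbpa from -0.039 to 1.31, Ceacam11 from -0.18 to 2.42 and Prl4a1 from -3.35 to 0.026.

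Without cells over 2 times the median UMIs, Plac8 was at 1.02, Krt8 at 0.74 and Hes1 at -0.021, all reversed. Without cells with blood transcripts, the megakaryocyte median was -0.23, Plac8 0.42, H2-Aa 1.27, Ppbp -1.34, Gp9 -0.9997 and Krt8 0.56, all reversed. Thinned counts reversed Plac8 (0.45) and Krt8 (0.23). Without clusters with markers of another cell type, the MHC class II median was 0.14, Plac8 0.59, H2-Aa 0.14, Tpbpa -0.14 and Tpbpb -0.11, all reversed. These are markers of blood cells and trophoblast, apart from Hes1, and they are not read as endothelial differences. RLE factors, plain totals and no filter left all 15 list medians and 51 named genes of this comparison in place.

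For macrophage-like against endothelial cells, the blood regulator median was 0.13 with plain totals, which also reversed the cell cycle median (-0.087). With each set left out, it ran from -0.017 to 1.002, so its sign rests on set 3, and H2-Eb1 ran from -0.22 to 3.61. The members of this list go both ways, which makes its median fragile. Without endothelial clusters with markers of another type, the trophoblast median was 0.30, reversed. Adding the Irf8 cluster moved 9 of 17 list medians and 6 of 54 genes and reversed none, and resolution 2 moved 10 and 6.

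No paired analysis was possible because cells of the Hoxa13 GFP table are tied to no sample, so day 12 was not compared with day 11. Since no label ties the barcode suffixes to samples, the Wald test, the gene set tests with preset and estimated correlation and their alternative were not run. Also not run were the comparison of annotated hemogenic endothelium, which the annotation does not name, the comparisons of days 12 and 10 with their weighting by mean per cell, the shares by day, and shares without erythroid cells, a class the annotation does not name.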

Other observations

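Clusters of TC-labelled cells, drawn after their Cdh5 level was seen, differed: Cdh5 was at 379 CPM (367 to 391) in 329 cells with Car2, Cdx2 and Serpinb9e among their top genes and 147.97 CPM of Flt1, and at 256 CPM (249 to 262) in 644 cells with Tpbpb, Prl8a9 and Prl3b1, where Flt1 reached 1621 CPM (1605 to 1637). Clusters led by Phlda2 (674 cells), Dio3 (508 cells) and Wfdc2 (269 cells) had 13.9, 15.7 and 5.78 CPM of Cdh5. A cluster with Hand1 and Tnfaip2 had 249 CPM of Cdh5 and 6.24 CPM of Flt1, so the pair of genes did not go together in every cluster.

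Of the tests below, those of blood cells, depth, cluster share, marker ratios and free globin RNA were chosen after the results were seen; the test of Cdh5 in cells without other markers and the test of erythroid doublets were written before their values were known, though the rule for reading the former was loosened after its value in set 1 was seen, and the free RNA test was split by set after its values were seen. Free RNA or doublets from endothelial cells could bring Cdh5 into TC-labelled cells. They would bring the endothelial markers in 1 ratio, but the percent of the endothelial level was at least 11.5 times the median of the other 11 markers for Cdh5 in each set. In TC-labelled cells with no UMI of those 11 markers, Cdh5 kept at least 54.1% of its level, but these were 7.97%, 20.5% and 25.9% of the cells, chosen toward low depth (median 16453.5 against 27213 UMIs in set 1), and the lower limit in set 1, 45.2%, lay under the bound of 50%, so the argument rests on the marker ratios. Flt1 stood at 137% and 122% of the endothelial level in sets 2 and 3, which argues against free RNA or doublets from endothelial cells as its whole source there. In set 1 it stood at 42.3%, which leaves that set open for Flt1. A hypothesis left for Cdh5 is that part of the TC-labelled cells may express it themselves, and no biological explanation was tested.

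The arterial profile of Cd44-positive endothelial cells may come from blood cells among them, from depth, or from a higher share of cells of the arterial clusters. Without cells that carry blood transcripts the arterial median was 1.09, and with thinned counts it was 1.17, both above the lower limit of 1.01. Thinned counts came from the same cells and the same Cd44 call, and random thinning leaves the ratio about as it was. Without TMM scaling, Gja5 was at 4.45, 2.36 and 1.11 CPM in HSC-labelled cells of sets 1, 2 and 3. In EC-labelled cells it was at 82.3, 289 and 76.2 CPM, so blood cells would lower the Gja5 level of Cd44-positive cells. Neither median therefore decides on the first pair of explanations. Outside the arterial clusters the median was 0.69, below the limit of 1.01 and above 0. Inside them, in sets 1 and 2, it was 0.06 (0.01 to 0.15), which goes against a large difference among arterial-cluster cells. Because the clusters were drawn from the same genes, cells just outside their borders leave the share of arterial cells open as an explanation.

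Globin transcripts in macrophage-like cells lay almost wholly in set 3, where 2 of 87 cells held at least 50% of the 20097 globin UMIs. By CPM without TMM scaling, Hbb-bs in set 3 was 1005 times its level in EC-labelled cells, which free RNA would not give. In set 2 it was 2.10 times that level, but Hba-a2 was at 11.6 against 0.959 CPM with TMM scaling and 1 cell held at least 50% of the 624 globin UMIs, so free RNA was left open there. Doublets with erythroid cells would bring Alas2 and Gypa along: 70 UMIs of this pair were seen, 112% (87.3 to 141) of the number that the ratio in the 17 erythroid-like cells gives. That number would go with a few doublets, or with cells that took up red cell content whole, which was not tested. But the mix of globins differed in set 3. Hbb-bs gave 4258 of 20097 globin UMIs in macrophage-like cells and 3261 of 140045 in erythroid-like cells. Of the 87 macrophage-like cells, 18 held over 100 globin UMIs. The range also treats UMIs of the same cell as independent, so the pair does not settle the source.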
